A study of Mus musculus with 6 samples.

How the data were processed

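Total RNA of 6 samples, 3 vector and 3 miR-34a, was labelled with biotin and hybridised to Affymetrix mouse arrays, per the labels. The table holds 22690 probe sets, fewer than the array model that the design text names. The values used are intensities on a linear scale as the authors deposited them in the value table of the series. The summarisation and normalization behind them are not given in the sources used here. Their medians per array lie close together, so they were taken as already scaled, and their lowest value is 1. No detection calls were used, so a dim probe set is not told apart from background. Precision is set by the number of arrays, 3 per group.

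Groups and replicate numbers come from the sample titles. Gene names come from the platform annotation, updated through Entrez identifiers with the GRCm38.p6 RefSeq gene table, from which no coordinates are given. Of the probe sets, 20393 had 1 gene symbol, 691 had several and 1606 were not listed; 20364 symbols were matched through the identifier and 29 kept as annotated. The 64 control probe sets were left out of the tests. Each gene was represented by the probe set with the highest mean among those with its symbol alone, giving 12393 genes from 20380 probe sets. Of the 2246 probe sets with several or no names, 204 passed the same threshold and are not named. Trp53 and the miR-34a host transcript had no probe set of their own, and Gapdh had control probe sets or ones shared with other genes.

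Values were analysed as log2(intensity + 16), which understates the change of low genes. Each gene was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with no trend and no block, and Benjamini-Hochberg adjustment over all genes at 0.05. Signed changes are miR-34a minus vector. A set of 32 gene lists, 19 of processes and 13 of other cell types, was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists; an estimated correlation per list and fry were alternatives. The lists hold 1136 symbols, of which 993 were measured, and some genes stand in more than 1 list. The result of 1 process list, which stayed in the tests and did not pass, is not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

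The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 15 largest rises and 15 largest falls among called genes whose groups did not overlap, up to 4 members per list with the smallest unadjusted p, and a fixed set of genes named for miR-34a, epithelial state and control. Alternatives were quantile normalization, median centring, leaving out the lower part of genes by level, pseudocounts of 1 and 64, the mean of all probe sets, a robust variance trend, array weights, the replicate number as a block, leaving out each array, and other thresholds. A planned test of miR-34a seed sites in 3' untranslated regions was not run, since no genome sequence was used here.

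The gene test was tested on simulated data for this comparison, with the 12393 genes and 200 of them changed. It recovered 0% of changes of 0.5 in log2, 85.5% of changes of 1 and 97.0% of changes of 2, with 0, 4 and 7 calls among the other genes. With nothing changed it made 0 calls. In the list test a simulated shift of the cell cycle list by -0.5 was called, and 0 of the 29 lists that share none of its members. In the real data the estimated correlation per list ran from -0.0227 to 0.758, against the preset 0.01. It was 0.758 for the fibroblast list and 0.717 for the cholesterol list. The simulations leave open how often lists with such correlated members are called falsely. They also leave open the effect of an array that stands apart from its group. Recovery where more than 200 genes change was not simulated, and the adjusted threshold depends on that number. In the real data 1456 genes passed, some with changes under 0.5, such as Arhgap1 at 0.33. The 0% at 0.5 therefore does not carry over to the real data.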

Results

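The series measured messenger RNA on 6 Affymetrix mouse arrays, with 3 samples of a vector control and 3 samples in which the microRNA miR-34a was inducibly expressed. Both came from 344SQ, a metastatic mouse lung cancer cell line with high Zeb1, a transcription factor that represses epithelial genes. The labels disagree on the material: the design text and the titles of the miR-34a samples speak of tumours grown in mice, and other fields speak of cultured cells. The levels of host cell genes that follow are of the brightest members of their lists. Among the mean levels of all genes, the collagen gene Col1a2 lay at the 98.0 percentile and the endothelial receptor gene Flt1 at 76.2. The macrophage protease gene Ctss lay at 92.7 and the complement gene C1qa at 91.1. Of the T and NK cell list, Thy1, which also stands in the fibroblast list, lay at 80.3, Zap70 at 74.9 and Cd3e at 43.5. The median level percentile of the whole list was 80.2 for fibroblast, 76.6 for macrophage, 44.4 for endothelial and 27.8 for T and NK cell. Levels of different probe sets do not give the share of host cells. Mature miR-34a was not measured, and no probe set was annotated to its host transcript. The medians of the deposited values ran from 466.7 to 484.2 per array. The number of arrays, 3 per group, limits the precision of every value below. Nothing in the labels says that the replicates came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

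The miR-34a arrays lay close together and the vector arrays did not. Vector 1 stood apart on the first principal component, which held 61.0% of the variance, at -43.33 against -5.42 and -8.75 for vector 2 and vector 3 and 16.25 to 21.66 for the miR-34a arrays. Across genes, Pearson's r was 0.993 between vector 2 and vector 3, 0.9686 and 0.9722 between vector 1 and these, and 0.9918 to 0.9955 between miR-34a arrays. No 2 arrays held the same values. The difference in log2 signal between 3' and 5' control probe sets, a sign of RNA integrity, was 0.43 ± 0.15 in vector and 0.57 ± 0.026 in miR-34a arrays for Actb (SD, n = 3; exact permutation test, two-sided, p = 0.4). For Gapdh it was -0.0068 ± 0.066 and 0.11 ± 0.014 (SD, n = 3; exact permutation p = 0.1, the smallest that this design allows).

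**Figure D1:**
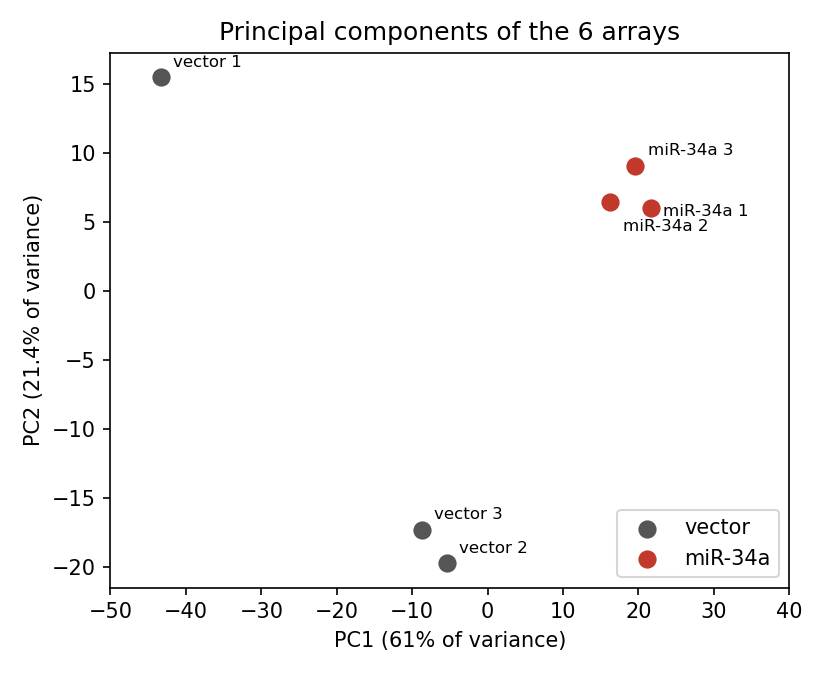
First and second principal components of the 12393 genes, in log2 units, for the 6 arrays, with the share of variance on each axis. Each point is an array; the miR-34a arrays (red) sit at 16.25 to 21.66 on the first component and vector 1 (grey) at -43.33.

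The comparison of miR-34a with vector asks which transcripts differ when miR-34a is expressed in 344SQ cells. Genes of 3 mast cell proteases were among the strongest rises: Tpsb2, a mast cell tryptase, was 11.5-fold higher in miR-34a samples, Cma1, a mast cell chymase, 7.62-fold, and Cpa3, the mast cell carboxypeptidase, 6.27-fold. The mast cell genes Mcpt4 at 1.14, Kit at 0.035 and Ms4a2 at 0.019 did not pass, and neither did the neutrophil and mast cell list (camera adjusted p = 0.432). Of 74 measured genes of cell division 64 changed by less than 0, and 50 passed as lower and 1 as higher. The list had a camera adjusted p of 9.54e-26, and an adjusted p of 0.142 with an estimated correlation. Those passing as lower numbered 20 without miR-34a 3, 26 without miR-34a 1 and 31 without miR-34a 2. The list's median, -0.57 over all arrays, ran from -0.6 to -0.5 when each array was left out in turn. Of 19 measured genes of cholesterol synthesis 18 changed by less than 0 and 8 passed as lower. This list had a camera adjusted p of 1.88e-08, and an adjusted p of 0.875 with an estimated correlation. Those passing as lower numbered 2 without miR-34a 3, 4 without miR-34a 1 and 5 without miR-34a 2. The list's median, -0.77 over all arrays, was -0.798, -0.806 and -0.729 in these fits and -0.564 without vector 1. The neutrophil chemokine gene Cxcl5 fell 9.34-fold and the neutrophil calcium-binding protein gene S100a9 7.89-fold, log2 changes of -3.22 and -2.98 that were -2.38 and -2.23 without vector 1.

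Of 12393 genes tested with limma, 1456 (11.7%) passed an adjusted p under 0.05, of which 805 were higher in miR-34a samples and 651 lower. At least 2-fold changes were found in 85 of the higher and 73 of the lower genes. The 3 values of one group all lay above those of the other in 4321 genes (34.9%, where chance gives 10%), among them each of the 1456. The count depended on single arrays: it was 631 without vector 3, 255 without miR-34a 1, 667 without miR-34a 2 and 226 without miR-34a 3. Without vector 2 it was 1256, and without vector 1 it was 2133, with 1247 genes higher. Each of these fits has 1 array fewer than the main fit, which by itself can lower a count. In none of them did any of the 1456 calls change sign. Of the 697 called genes with several probe sets, 166 had probe sets of opposite sign. Higher and lower calls were unevenly placed in the genome: among genes in the regions with fewest neighbouring genes 111 were higher and 242 lower, and in those with most 253 and 38.

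Among the largest rises, Tpsb2 went from 6.82 ± 0.137 to 10.35 ± 0.35 in log2 units (SD, n = 3), a change of 3.53 ± 0.177 (SE; limma adjusted p = 0.000844). A second Tpsb2 probe set changed by 0.10. Cma1 changed by 2.93 ± 0.183 (limma adjusted p = 0.00143), Cpa3 by 2.65 ± 0.173 and Fcer1a, the alpha chain of the high-affinity IgE receptor, by 1.93 ± 0.15, and each of these 4 genes kept its call without any 1 array. The size for Fcer1a depended on the pseudocount, with 2.40 at a pseudocount of 1 and 1.23 at 64. The chloride channel regulator gene Clca3a1 rose by 3.32, the kinase gene Nrk by 2.95, the small heat shock protein gene Hspb1 by 2.71 and the 5-oxoprolinase gene Oplah by 2.43. The Wnt ligand gene Wnt10a rose by 2.17 and the growth factor gene Igf1 by 2.15. Wif1, which encodes a secreted Wnt inhibitor, was higher with a size set by the pseudocount, since its vector mean of 4.747 lay near the lowest values: 2.59, and 3.76 at a pseudocount of 1 and 1.48 at 64. The adhesion molecule gene Icam1 rose by 2.05, the tight junction gene Ocln by 1.98, the chitinase-like gene Chil4 by 1.96 and the glutathione transferase gene Gstm1 by 1.82. Other probe sets of Clca3a1, Nrk, Igf1 and Gstm1 changed by as little as 1.82, 0.104, 0.563 and 0.341. In the 6 fits that left out 1 array, the call of Chil4 was kept in 5, that of Clca3a1 in 4, those of Hspb1 and Igf1 in 3 and that of Wnt10a in 2. Without vector 1, Hspb1 changed by 2.02.

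Among the largest falls, Cxcl5 changed by -3.22 ± 0.748 (SE; limma adjusted p = 0.0368), from 11.07 ± 1.54 to 7.85 ± 0.76 (SD, n = 3). Klrc1, a receptor gene of natural killer cells, changed by -3.00 ± 0.153 (adjusted p = 0.000844), S100a9 by -2.98 ± 0.591, Tm4sf4 by -2.68 and Ambp by -2.66. The cytokine gene Il1a fell by 1.89, the acyl-CoA synthetase gene Acsbg1 by 1.80, the connexin gene Gjb5 by 1.71, the collagen lysyl hydroxylase gene Plod2 by 1.70 and the nucleosome-binding protein gene Hmgn5 by 1.67. Nexmif and the transcription factor gene Pdx1 each fell by 1.59, the decoy receptor gene Tnfrsf23 by 1.58, Ifitm1 by 1.55 and the adrenomedullin gene Adm by 1.52. In the 6 fits that left out 1 array, the call of Tm4sf4 was kept in 5, those of Nexmif and Tnfrsf23 in 4, those of S100a9 and Adm in 3 and those of Cxcl5, Ambp, Il1a, Gjb5 and Ifitm1 in 2. Without vector 1, Cxcl5 changed by -2.38, S100a9 by -2.23 and Ambp by -1.92, and without vector 3 Cxcl5 by -3.89 and Ambp by -3.28.

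The cell cycle and DNA replication list fell by a median of 0.57 (camera adjusted p = 9.54e-26; adjusted p = 0.142 with an estimated correlation). Of its 74 measured members, 50 were lower and 1 higher over all genes tested, and 54 and 2 when adjusted over the list alone. The chromatin protein gene Hmgb2 changed by -1.46 ± 0.0918, the checkpoint kinase gene Chek1 by -1.25 ± 0.0912, the spindle kinase gene Ttk by -1.22 ± 0.0954 and the kinetochore gene Cenpf by -1.34 ± 0.114 (SE). Other probe sets of Chek1 and Cenpf changed by as little as -0.088 and -0.041. The single higher member was Ccnd3, a D-type cyclin gene, at 0.48, named after its value was seen. Lower members numbered 20 without miR-34a 3, 26 without miR-34a 1 and 31 without miR-34a 2 or with the replicate block. The list's median was -0.53 without vector 1, -0.512 without miR-34a 3, -0.578 without miR-34a 1 and -0.564 without miR-34a 2.

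The cholesterol biosynthesis list fell by a median of 0.77 (camera adjusted p = 1.88e-08; adjusted p = 0.875 with an estimated correlation), with 8 of 19 members lower, 0 higher, and 12 lower when adjusted over the list alone. Idi1, an isoprenoid isomerase gene, changed by -1.52 ± 0.138, the sterol oxidase gene Msmo1 by -1.35 ± 0.171, the sterol transport gene Stard4 by -1.27 ± 0.169 and the HMG-CoA synthase gene Hmgcs1 by -0.84 ± 0.113 (SE). Vector 1 was the highest array, with a list median of 0.39 above the vector mean, and without it the list's median was -0.56. Lower members numbered 2 without miR-34a 3, 4 without miR-34a 1 and 5 without miR-34a 2. The list's median in these fits was -0.798, -0.806 and -0.729. The hypoxia and glycolysis list had a median of -0.041 (camera adjusted p = 0.0128; adjusted p = 0.875 with an estimated correlation; adjusted p = 0.0501 without miR-34a 3). Its 6 lower members of 39 (9 lower and 1 higher when adjusted over the list alone) included Adm, the mTOR inhibitor gene Ddit4 at -1.14, the hexokinase gene Hk2 at -0.76 and Hif1a at -0.38. Other probe sets of Hif1a ran from -1.89 to -0.165. The list's median was -0.108 without vector 1, -0.0782 without vector 2, -0.0648 without vector 3, -0.0778 without miR-34a 1, -0.0793 without miR-34a 2 and -0.061 without miR-34a 3, and it was -0.182 with the lower part of genes by level left out, -0.135 with the mean of all probe sets and -0.114 with array weights. Its lower members numbered 3 without vector 3, 2 without miR-34a 2 or with the replicate block and 0 without miR-34a 1 or miR-34a 3.

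**Figure D2:**
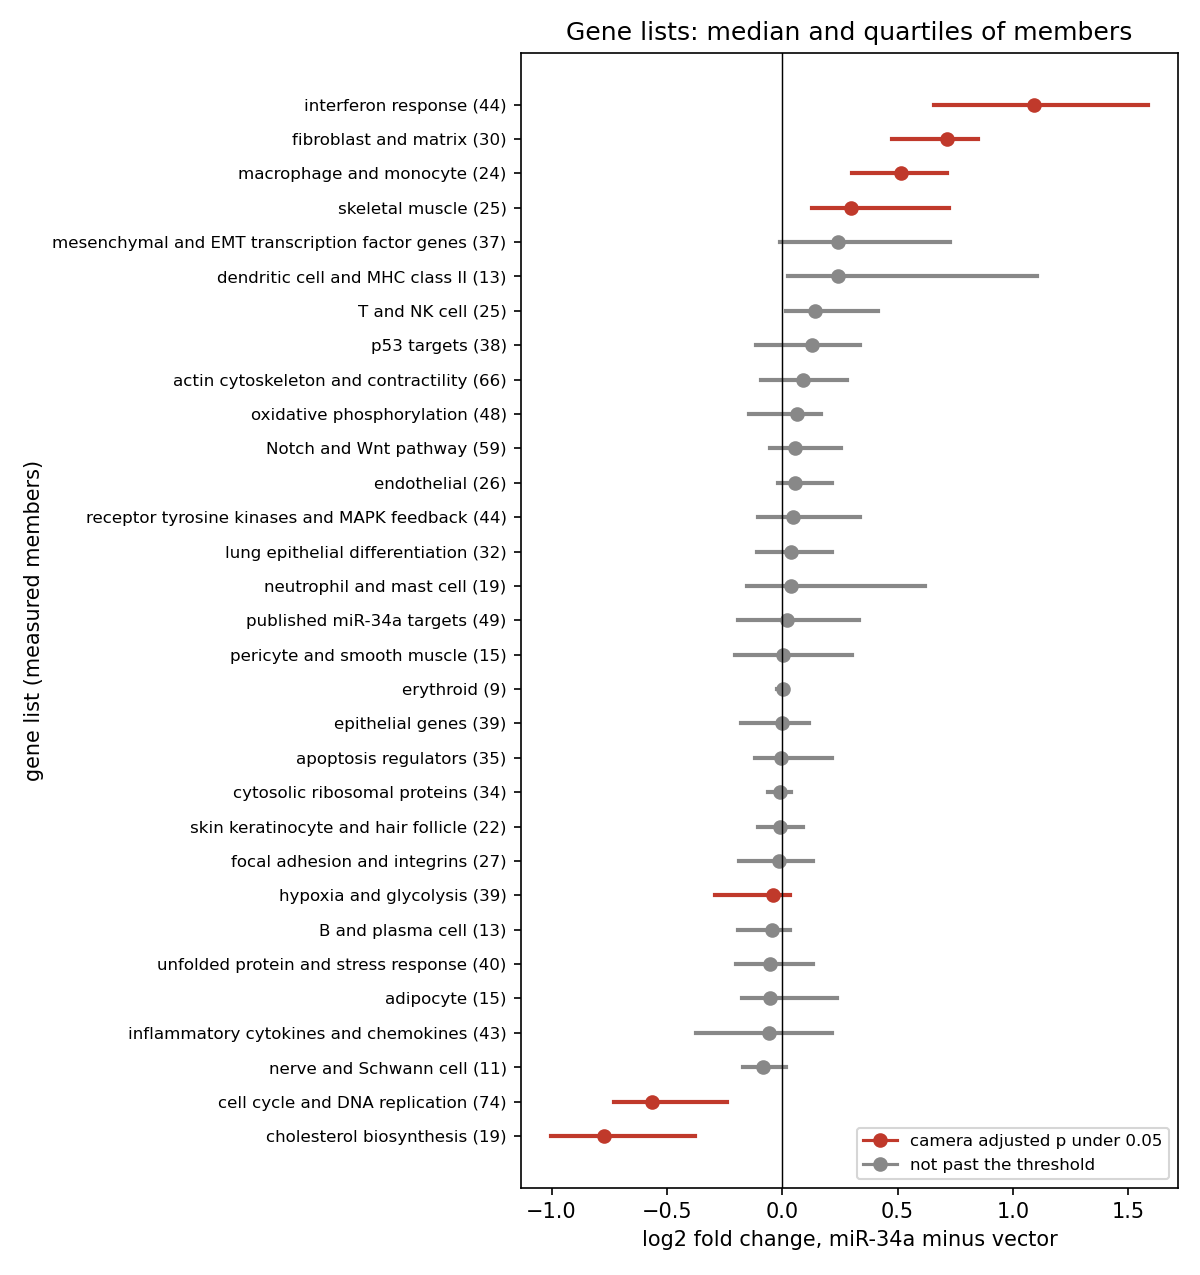
Median log2 fold change, miR-34a minus vector, of the measured members of 31 of the 32 gene lists (points) with the lower and upper quartiles (bars); the number of measured members follows each name. The 7 lists past the camera threshold at the preset correlation are red, from interferon response at 1.09 to cholesterol biosynthesis at -0.77. With an estimated correlation 0 lists passed.

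The interferon response list had a median 1.09 higher in miR-34a samples (camera adjusted p = 1.51e-06; adjusted p = 0.875 with an estimated correlation), and 5 of its 44 members passed, all higher, or 6 when adjusted over the list alone. They included the peptide loading gene Tapbp at 0.93 ± 0.171, Ifi35 at 0.78 ± 0.15, the immunoproteasome gene Psmb10 at 0.95 ± 0.194 and the antiviral gene Rsad2 at 0.69 ± 0.146 (SE). Another Tapbp probe set changed by 0.146, and other Rsad2 probe sets by 0.267 and 1.44. Vector 1 was the low array, with a list median 1.04 below the vector mean (-1.04), against 0.27 and 0.67 for vector 2 and vector 3 and 0.83 to 1.41 for the miR-34a arrays. Without vector 1 the list's median was 0.55 and its adjusted p 2.02e-06, and 14 members passed. Members past the threshold numbered 8 without vector 3, 1 without vector 2 or miR-34a 2, and 0 without miR-34a 1 or miR-34a 3 or with the replicate block.

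The fibroblast and matrix list had a median of 0.72 (camera adjusted p = 0.000402; adjusted p = 0.875 with an estimated correlation). Its 4 higher members of 30, the same number when adjusted over the list alone, were the collagen genes Col6a1 at 0.70 ± 0.0976 and Col6a2 at 0.78 ± 0.114, the procollagen processing gene Pcolce at 0.81 ± 0.148 and the surface glycoprotein gene Thy1 at 1.73 ± 0.377 (SE). Vector 1 was again low, at -0.91, and without it the median was 0.21 and the adjusted p 0.179. Members past the threshold numbered 2 without vector 3 or with the replicate block, 1 without miR-34a 1 and 0 without miR-34a 3. The macrophage and monocyte list had a median of 0.51 (camera adjusted p = 0.0141; adjusted p = 0.875 with an estimated correlation), 0.30 and adjusted p = 0.0907 without vector 1, which stood at -0.52. Of its 24 members 3 were higher and 1 lower, and 6 and 1 when adjusted over the list alone. Higher members numbered 8 without vector 1, 5 without vector 2 and 0 without vector 3, miR-34a 1, miR-34a 2 or miR-34a 3. The complement gene C1qb changed by 1.13, the Fc receptor genes Fcgr1 and Fcer1g by 0.98 and 0.48, and the mannose receptor gene Mrc1 by -0.99 ± 0.0814 (SE; limma adjusted p = 0.00264). The skeletal muscle list had a median of 0.30 with 0 of 25 members past the threshold, over all genes or over the list alone (camera adjusted p = 0.0407; adjusted p = 0.875 with an estimated correlation). Its adjusted p was 0.0907 without vector 1, 0.117 without vector 2, 0.147 without miR-34a 1 and 0.294 without miR-34a 3, where its median was 0.192. Without miR-34a 2, 8 members passed. The changes of Ckm, Myl1, Atp2a1 and Des ran from 0.28 to 0.83. In the fits that left out 1 array, Ckm ran from 0.238 to 0.437, Myl1 from 0.505 to 1.12, Atp2a1 from 0.173 to 0.353 and Des from 0.429 to 1.07. With an estimated correlation, 0 of the 32 lists passed after adjustment and 1, the cell cycle list, had an unadjusted p under 0.05. By fry, 1 list passed, the same list (adjusted p = 0.00155).

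**Figure D3:**
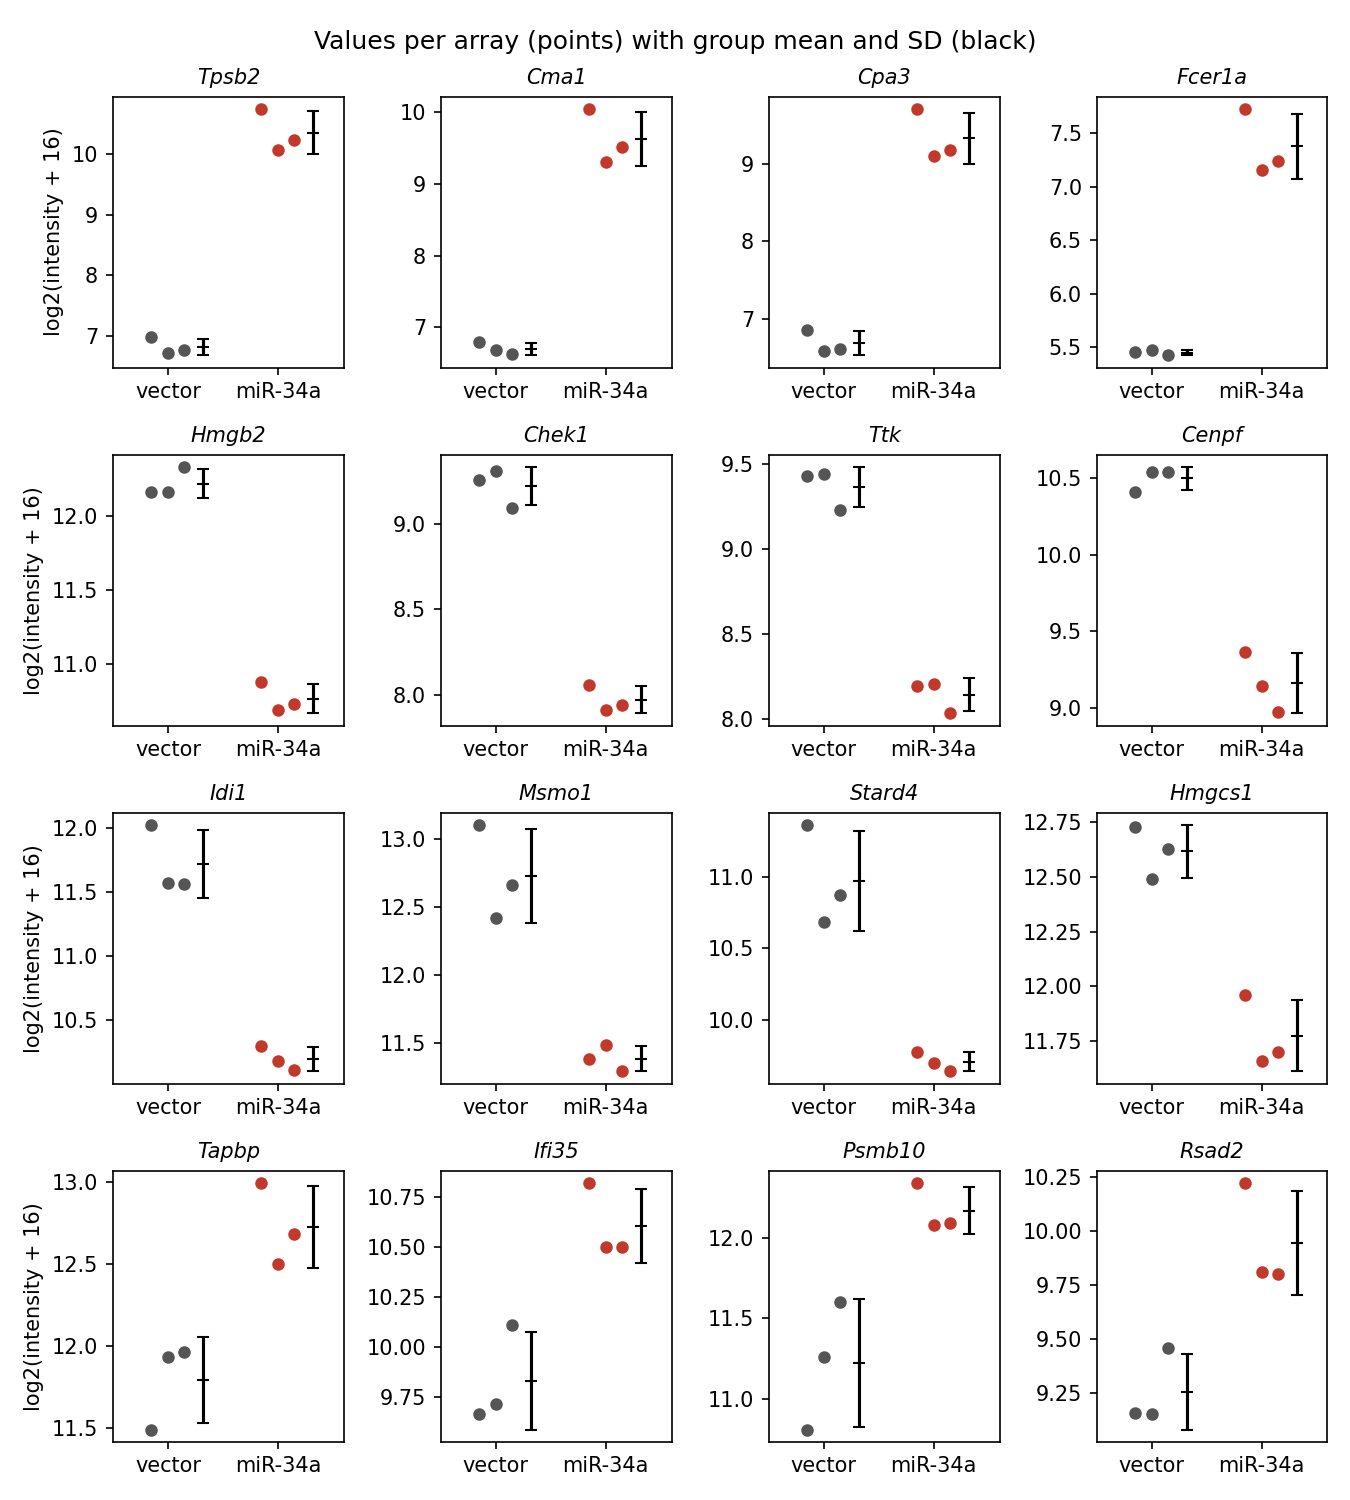
Log2(intensity + 16) of 16 genes on each array (points, vector grey, miR-34a red), with the group mean and SD in black (n = 3), by row: mast cell, cell cycle, cholesterol and interferon genes; each vertical axis has its own range and does not start at 0. In each gene the 3 miR-34a values lie on one side of the 3 vector values, as for Tpsb2 with means of 6.82 and 10.35. This follows from the choice of called genes with the smallest unadjusted p in their lists. Each of the 1456 called genes had groups that did not overlap.

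Other marker lists did not pass camera. The neutrophil and mast cell list (median 0.037, adjusted p = 0.432) had 4 higher members, Tpsb2, Cma1, Cpa3 and Fcer1a, and 1 lower, S100a9, of 19, and 5 and 2 when adjusted over the list alone. In the T and NK cell list (0.14, 0.105) Icos at 0.45 and Thy1 rose, and Cd3d at 0.48 and Il7r at 0.27 did not pass. Thy1 also stands in the fibroblast list. With the mean of all probe sets this list passed (adjusted p = 0.0408), and 0 members passed without vector 3, miR-34a 1, miR-34a 2 or miR-34a 3 or with the replicate block. The dendritic cell and MHC class II list had a median of 0.24 (adjusted p = 0.211) and 0 members past the threshold; the values of Ciita and H2-DMa were 0.48 and 1.11. Without vector 1, 4 members passed, and the values were 0.37 and 0.387. The endothelial list had a median of 0.055 (0.668), with Emcn at -0.25 and Tek at 0.23, and the pericyte and smooth muscle list 0.0051 (0.738), with Abcc9 lower at -0.86. The B and plasma cell list had a median of -0.045 (0.67), the adipocyte list -0.053 (0.911), the erythroid list 0.0016 (0.815), the skin keratinocyte and hair follicle list -0.011 (0.668) and the nerve and Schwann cell list -0.081 (0.395). In these 5 lists Pnpla2, a lipase gene, was the member past the threshold, at 0.37, and 0 passed when adjusted over the list alone. So adjusted, 2 T and NK cell genes were higher, 1 pericyte gene was lower and 0 endothelial or dendritic cell genes passed.

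The inflammatory cytokine and chemokine list (median -0.056, adjusted p = 0.295) had 6 lower and 4 higher members of 43, and 8 and 4 when adjusted over the list alone. Without vector 1 it passed, with a median of -0.1 (adjusted p = 0.0256) and 9 lower members. Lower and higher members numbered 3 and 2 without vector 2, 4 and 1 without vector 3, 1 and 2 without miR-34a 2 and 1 and 1 without miR-34a 1 or miR-34a 3. The chemokine gene Cxcl2 changed by -1.22 ± 0.139 and the cytokine gene Il18 by 0.51 ± 0.101 (SE), beside Cxcl5, S100a9 and Icam1 above. In the oxidative phosphorylation list (0.065, 0.911) 4 of 48 members rose and 4 fell, or 7 and 6 when adjusted over the list alone. Higher and lower members numbered 7 and 4 without vector 1, 2 and 2 without vector 3, 0 and 2 without miR-34a 1, 2 and 3 without miR-34a 2 and 0 and 1 without miR-34a 3. Cytochrome c, Cycs, changed by -0.82 and the complex I gene Ndufa5 by -0.88, while the complex I genes Ndufs8 and Ndufv1 changed by 0.60 and 0.46. The unfolded protein and stress response list (-0.053, 0.211) had 5 lower members of 40, among them the chaperone genes Hsph1 at -0.98, Hspd1 at -0.59 and Pdia6 at -0.49, and 1 higher, Hspb1, or 6 and 2 when adjusted over the list alone. It passed with the mean of all probe sets (adjusted p = 0.0408), and 0 members passed without miR-34a 1 or miR-34a 3. Its lower members numbered 3 without vector 2 or miR-34a 2. Of 34 cytosolic ribosomal protein genes 0 passed, over all genes or over the list alone (median -0.0097, adjusted p = 0.497), and Rpl14 and Rps27 changed by -0.38 and 0.49.

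Published targets of miR-34a did not shift as a list (median 0.019, camera adjusted p = 0.668). Of 49 measured, 5 were lower and 3 higher, and 6 and 4 when adjusted over the list alone. Without miR-34a 1 or miR-34a 3, 1 was lower and 1 higher, without vector 3 or miR-34a 2, 2 and 2, and without vector 1, 7 and 3. The receptor tyrosine kinase gene Met fell by 1.05 ± 0.243 (SE; limma adjusted p = 0.0366), from 8.56 ± 0.534 to 7.51 ± 0.0731 (SD, n = 3), the cell cycle regulator gene E2f5 by 0.85 and the Notch ligand gene Dll1 by 0.76. Vamp2 rose by 0.89 and Mycn by 0.45. Arhgap1 was 0.33 ± 0.0709 higher (SE; adjusted p = 0.0293), its other probe set changed by -0.42, and its call was kept in 1 of the 6 fits that left out 1 array. Bcl2 at -0.012, Cdk4 at 0.026, Cdk6 at -0.45, Ccnd1 at 0.14, Sirt1 at -0.34, Cd44 at 0.41, Myc at -0.077, E2f3 at 0.097, Notch1 at 0.35, Jag1 at -0.46 and Axl at 0.50 did not pass. Of the 2 Axl probe sets, at 0.497 and 0.73, 1 passed as higher when all probe sets were tested. Without vector 1 the values of Ccnd1, Cd44 and Axl were 0.034, 0.131 and 0.285, those of Cdk4, Myc, E2f3 and Bcl2 were -0.054, -0.029, 0.154 and -0.019, and Jag1 passed at -0.59 (adjusted p = 0.0265). In the 6 fits that left out 1 array, Cdk6 ran from -0.62 to -0.191, the latter without vector 3, Sirt1 from -0.493 to -0.213, the latter without miR-34a 3, Bcl2 from -0.0516 to 0.0412, Myc from -0.152 to 0.0176, Ccnd1 from 0.0336 to 0.22 and E2f3 from 0.0283 to 0.154. The call of Met was kept in 2 of the 6 fits that left out 1 array.

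The epithelial list had a median of -3.24e-05 (camera adjusted p = 0.911), with 4 of 39 members higher and 1 lower, or 4 and 2 when adjusted over the list alone. Without miR-34a 1 or miR-34a 3, 2 were higher and 0 lower, and without vector 3 or miR-34a 2, 3 and 0. Ocln, Spint1 at 1.37 and Mal2 at 1.57 rose and the tight junction gene Tjp1 fell by 0.44. Cdh1, which encodes E-cadherin, changed by 0.077 ± 0.0798 and Epcam by 0.42 ± 0.503 (SE), and neither passed. The mesenchymal and EMT transcription factor list (0.24, 0.211) had 4 higher members of 37, among them Twist1 at 1.57 and Pmp22 at 0.55, and 3 lower, among them S100a4 at -0.95 and Bmi1 at -0.48, or 5 and 4 when adjusted over the list alone. It passed without vector 2 (adjusted p = 0.0262). Higher and lower members numbered 7 and 5 without vector 1, 1 and 2 without vector 3 or miR-34a 2 and 0 and 0 without miR-34a 1 or miR-34a 3. Zeb1 changed by 0.027 ± 0.0976, Zeb2 by 0.73 ± 0.327, Vim by 0.092 ± 0.0829 and the N-cadherin gene Cdh2 by 2.00 ± 0.935 (SE), and none passed (limma adjusted p = 0.896, 0.199, 0.524 and 0.216). Without vector 1, Cdh2 changed by 0.77 with an adjusted p of 0.0167, and the values of Zeb1, Zeb2, Vim and Epcam were -0.061, 0.324, 0.043 and -0.215.

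Other process lists did not pass camera. In the actin cytoskeleton list (median 0.09, adjusted p = 0.399) 5 of 66 rose and 1 fell, with rises for Limk2 at 0.53, Diaph1 at 0.61, Cnn2 at 0.63 and Coro1a at 0.81. Other probe sets of Limk2, Diaph1 and Coro1a changed by as little as 0.271, 0.016 and 0.212. Itgb5 at 1.24 and Ilk at 0.45 rose among 27 focal adhesion genes (-0.014, 0.67). Among 38 p53 targets (0.13, 0.656) Casp1 at 1.605 and Xpc at 0.45 rose, Gadd45a at -1.09 and Tgfa at -0.61 fell, and Cdkn1a at -0.24 did not pass. Without vector 1 the value of Cdkn1a was 0.00863. In the apoptosis list (-0.0051, 0.911) 3 of 35 rose, among them Tnfrsf1a at 0.44, and 4 fell, among them Casp8 at -0.73. Wnt7a at 1.37 and Nkd2 at 0.65 were among 4 higher members of 59 in the Notch and Wnt list (0.056, 0.399), with 1 lower, Dll1. Ddr1 at 0.63 and Ephb4 at 0.65 rose and Spred2 at -0.36 fell beside Met among 44 genes of the receptor tyrosine kinase list (0.046, 0.67). Cebpa, at 0.89, was the member past the threshold among 32 lung differentiation genes (0.038, 0.738). When adjusted over the list alone, higher and lower members numbered 5 and 1 for actin, 2 and 0 for focal adhesion, 2 and 2 for p53 targets, 5 and 4 for apoptosis, 4 and 1 for Notch and Wnt, 2 and 1 for receptor tyrosine kinases and 0 and 0 for lung differentiation. Without miR-34a 1, and without miR-34a 3, over all genes 0 members passed for focal adhesion, p53 targets, receptor tyrosine kinases and lung differentiation, and 1 rose and 0 fell for Notch and Wnt. Without vector 1, higher and lower members numbered 6 and 3 for p53 targets, 5 and 3 for receptor tyrosine kinases, 7 and 2 for Notch and Wnt, 4 and 3 for lung differentiation, 3 and 2 for focal adhesion, 8 and 3 for actin and 5 and 4 for apoptosis. Without vector 3 they numbered 2 and 0 for p53 targets, 1 and 0 for receptor tyrosine kinases, 1 and 1 for Notch and Wnt and 1 and 2 for apoptosis. Without miR-34a 2 they numbered 1 and 0 for p53 targets, 2 and 0 for receptor tyrosine kinases, 2 and 1 for Notch and Wnt, 0 and 0 for focal adhesion, 2 and 2 for apoptosis and 0 and 1 for lung differentiation, and without vector 2, 4 and 1 for p53 targets, 2 and 1 for receptor tyrosine kinases and 0 and 0 for lung differentiation. Of actin genes 0 rose without miR-34a 1, 1 without vector 3 or miR-34a 3, and 2 without miR-34a 2. Of apoptosis genes 0 rose and 2 fell without miR-34a 1, and 0 and 1 without miR-34a 3. Probe sets of opposite sign were present for Vamp2, Mycn, Ddr1, Spred2, Pdia6, Tgfa, Pnpla2, Icos, Arhgap1, Cd44, Zeb1 and Des. The other probe sets of Cd44 and Zeb1 changed by -0.208 and -0.172. The sign of the median, the mean and the test differed in 8 of the 32 lists: published targets, focal adhesion, epithelial, apoptosis, stress response, pericyte, adipocyte and erythroid.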

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

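All alternatives here were fixed before the data were examined. With array weights the genes changed numbered 3238 (1919 higher, 1319 lower), and over all probe sets 2938 (1368 higher, 1570 lower). At least 2-fold changes left 158 (85 and 73), and an adjusted p under 0.10 gave 2422 (1429 and 993). The replicate numbers did not pair the arrays, with correlations of deviations between equal numbers of -0.17, -0.094 and -0.081; with the replicate block 522 genes passed (250 higher, 272 lower). Leaving out 1 array gave 226 to 2133 genes, 98 to 1247 higher and 128 to 886 lower. These fits all leave the same degrees of freedom, fewer than the main fit, so that does not account for the range between them. The highest count, 2133, was without vector 1, which had the lowest array weight, 0.267. Causes of the range were not tested. Quantile normalization gave 1455 genes (741 higher, 714 lower), median centring 1396 (724 and 672) and the mean of all probe sets 1476 (750 and 726). The excess of higher over lower genes was thus smaller than in the main fit (805 and 651). Without vector 1, 1407 of the 1456 genes kept their call.

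With an estimated correlation 0 of the 7 lists passed, with adjusted p of 0.142 for cell cycle and 0.875 for hypoxia, cholesterol, interferon, macrophage, fibroblast and skeletal muscle. By fry 1 passed, with adjusted p of 0.0706 for hypoxia, 0.0921 for cholesterol, 0.174 for interferon, 0.357 for macrophage and skeletal muscle and 0.265 for fibroblast. The macrophage list had 0.088 with the lower part of genes by level left out and 0.0528 with array weights. Leaving out 1 array gave 0.00657 to 0.0501 for hypoxia, 0.000273 to 0.0907 for macrophage, 2.47e-07 to 0.179 for fibroblast and 8.32e-07 to 0.294 for skeletal muscle, and 5 to 7 lists; the cause was not tested. Lists also gained a call: inflammatory cytokines without vector 1 (0.0256), mesenchymal genes without vector 2 (0.0262), and T and NK cell and stress response with the mean of all probe sets (0.0408 each, 9 lists in all). Arhgap1 changed by -0.045 with the mean of its probe sets, which average opposite signs. Among named genes, 284 values lost the call and 48 gained it over all settings. The seed site test was not run. Signal over background per probe set was not used here, so the dimmest genes have the least certain folds.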

Other observations

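The tests of lower cancer cell share, larger host cell share, single arrays and X linkage, and the division of mast cell genes from their list, were chosen after the results were seen. Called genes were unevenly placed in the genome. Of 402 measured X-linked genes, 51 were lower and 9 higher, against the split elsewhere (Fisher's exact test, two-sided, p = 9.14e-11, adjusted p = 1.83e-09 over 20 chromosomes). At an adjusted p under 0.05, lower genes were also over-represented on chromosomes 8 (46 lower, 17 higher) and 6 (61 and 33), and higher genes on 5 (25 and 73), 7 (29 and 66), 11 (42 and 92), 15 (11 and 48), 17 (19 and 61) and 19 (14 and 37). These tests count genes, which share the same arrays and are not independent replicates. Their p-values do not measure the spread between samples. Genes were divided into 5 bins by the number of protein-coding genes within 500 kb. In the sparsest bin 111 genes were higher and 242 lower, and in the densest 253 and 38. Across 12367 genes, which are not independent replicates, Spearman's rho of log2 change with density was 0.17. The difference of vector 1 from the other vector arrays, within 1 group, had a rho of 0.11 with density. GC content was not tested, since no genome sequence was used here.

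Of the 10 splits of the 6 arrays, 1, the real one, gave 1456 genes, and the highest of the others gave 0. This design has too few splits for a share under 0.05.

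The fall of cell cycle genes (adjusted p = 0.142 with an estimated correlation) was set against 3 technical explanations. A lower share of cancer cells would lower their abundant epithelial genes alike. The 10 most abundant, among them Krt18, Krt8 and Cdh1, had a median change of 0.015 (SD 0.25) against -0.57. They ran from -0.44 for Tjp1 to 0.48 for Dsg2. Krt18 and Krt8, at mean levels of 14.53 and 14.39, lay near the highest signals, where a fall may be understated. So the median argues against a share low enough to give -0.57, and a smaller difference in share stays open. Without any 1 array the weakest median was -0.5, which argues against vector 1 alone. With the trend on gene density and level removed the median was -0.55 (bootstrap SE 0.056). This SE treats genes as independent replicates, which they are not, and does not measure the spread between samples. GC content, and a difference in handling between groups that the labels do not record, stay open; lower proliferation with miR-34a may be a hypothesis that these data do not test.

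Of 7 measured mast cell genes (median change 1.93, that of Fcer1a, whose size depends on the pseudocount), divided from their list after the results were seen, 4 rose, and Mcpt4 at 1.14, Kit at 0.035 and Ms4a2 at 0.019 did not pass; the whole list did not pass camera (adjusted p = 0.432). A larger share of all host cells would raise other host genes alike. The 41 endothelial and pericyte genes had a median of 0.032 (SD 0.33), while the fibroblast and macrophage lists stood at 0.72 and 0.51 (0.21 and 0.30 without vector 1). The endothelial and pericyte lists lay at median level percentiles of 44.4 and 46.8. These genes did not rise as a set, but dim members were not told apart from background, so a larger host share stays open. Without any 1 array the lowest median was 1.76, so vector 1 alone does not account for the 4 rises. More mast cells in the miR-34a samples, or expression of these genes in other cells, may be candidate explanations; neither was tested, and the labels disagree on tumour or culture.

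The fall of X-linked genes had a coefficient of -0.14 (SE 0.018) on log2 change. With gene density, gene length and level in the model the coefficient was -0.12 (SE 0.018), so the trend on density does not account for it. These SEs, and the interval below, treat genes as independent replicates, which they are not. Lower X dosage in the miR-34a cells might put most expressed X-linked genes below the autosomal median: 118 of 157 in the upper part by level were (75.2%, exact 95% interval 67.6 to 81.7). The bound of 75% was chosen after the X-linked calls were seen, and the requirement that the whole interval clear it was added after this value was seen. The bound lies inside the interval, so dosage cannot be told apart from other causes. GC content stays open.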
